A study of Mus musculus with 6 samples.

How the data were processed

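Whole lungs were collected from 6 mouse embryos at embryonic day 18, and 1 RNA-seq library was made from each. Per the labels' protocols, total RNA was taken from the whole lung with a column kit and libraries were made with a stranded mRNA kit. The labels name 3 libraries as controls, which carry the Prx1Cre transgene with 1 floxed and 1 intact Gata4 allele, and 3 as Gata4 CKO, which carry Prx1Cre with 1 floxed and 1 deleted allele. The deposited table gives whole-number read counts per Ensembl gene with no scaling, per the file headers and the values. The submitters' processing notes name STAR 2.7.10a, featureCounts 2.0.1 and DESeq2 1.36.0 and the builds GRCm38 and mm10, with no role or order. The annotation release, the strand setting and any filter on reads are not given in the sources used here. Reads of genes that overlap on opposite strands, or that have near-identical copies, may therefore be split between genes in an unknown way.

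The table held 55335 genes, of which 23377 had no symbol. The symbols of 23239 of these were taken from a reference table by gene ID. Where several rows shared a symbol, the row with most reads kept it, and 180 rows went by their gene ID. Of 771 gene list entries, 770 were found in the table. No column of per-sample values was left unused. Gene positions come from GENCODE mouse release 21 on GRCm38, which held 99.9% of the tested genes. Total counts ranged from 15156415 to 30848948 per library. With 3 libraries per group, an exact permutation test of 1 value cannot go below p = 0.1, and every test was two-sided.

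The main comparison was Gata4 CKO minus control over all 6 libraries, without covariates. Genes were filtered with filterByExpr (smallest count 10, smallest total count 15), which left 17075. Counts were scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 with robust dispersions, under R 4.3.3. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values were computed from the TMM-scaled library sizes. The 51 gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Lists needed at least 3 tested members, and the same lists were tested with a correlation estimated from the data and with fry. A list's value is the mean log2 fold change of its tested members. A list's score in a library is the mean log2 CPM of its members minus the mean over the controls.

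The groups, the tests, the gene lists, the other settings to be tried and the rule for named genes were fixed before the data were examined. The rule names Gata4, sex-linked genes and a fixed set of lung genes whatever their values. It also names the genes with the largest changes past the threshold, with at least 1 CPM on average, every Gata4 CKO library on the same side of every control, and no clone-type symbol. Where none pass in a direction, it names the 5 genes with the smallest p that meet the other conditions. For each list it names up to 3 members with the smallest p where none pass. The genes H2-Eb1, H2-Ab1, H2-DMb1 and Alb were chosen after their values were seen. A result for 1 gene that the rule names is not reported here.

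The settings chosen then were other scalings, filters and tests (DESeq2 1.42.0, limma-voom, and limma-voom with quality weights), the replicate number as a block, and a number within the authors' column labels as a term. Each library was also left out in turn, globin genes were left out, Xist was used as a covariate, and the threshold was set to 0.10. The labels give that number (4229, 4503 or 4723) no meaning. It is 4229 in control 1, control 2 and Gata4 CKO 1, 4503 in control 3, and 4723 in Gata4 CKO 2 and 3. Further settings were chosen after the data were seen. These removed a trend with transcript length and GC content (splines with 5 degrees of freedom) as an offset, combined that offset with the label number as a term, left out control 3 and Gata4 CKO 1 together, and ran DESeq2 without Gata4 CKO 1.

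The pipeline was tested on simulated data with 200 changed genes. For the comparison of Gata4 CKO with control, at the spread of all 6 libraries, it recovered 52% of the genes changed 2-fold among 16808 tested, with 13 false calls. It recovered 1% of those changed 1.5-fold among 16825, with 0 false calls, and 94.5% of those changed 4-fold among 16832, with 6 false calls. At the spread without Gata4 CKO 1, it recovered 80.5% of 2-fold changes among 16844 genes. When the simulated mitosis list alone was lowered 2-fold, camera called 1 list, with a mean log2 fold change of -1.05. Each simulated gene took its spread from the trend with expression level, without the length and GC trend of any library or structure among the samples. The share recovered in the real data may therefore be lower. The simulated genes varied independently of each other, while the correlation estimated for the real mitosis list was 0.847. The simulation therefore does not show how often camera at its preset correlation calls lists falsely in these data.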

Results

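Bulk RNA-seq was used to compare the lungs of mouse embryos that differ in Gata4, a zinc-finger transcription factor of the heart and of mesoderm. Prx1Cre drives Cre recombinase in the lateral plate mesoderm, which gives rise to the connective tissue of the diaphragm. Per the submitters' design text, its use with a floxed Gata4 allele leads to diaphragm defects and small lungs with less cell proliferation. The comparison asks which genes differ between such lungs and control lungs at embryonic day 18. Each group had 3 libraries, described by the labels as biological replicates, so p-values of single genes measure the spread between embryos. Camera p-values at the preset correlation compare a list with the other genes, taking its genes as nearly independent. They do not measure the spread of the list between embryos. Total counts were 21295440, 20851989 and 30848948 in controls 1, 2 and 3, and 20833883, 15156415 and 29749277 in Gata4 CKO 1, 2 and 3.

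Gata4 (ENSMUSG00000021944, chromosome 14, 63198922 to 63271692, minus strand, GRCm38, protein-coding) had 84, 63 and 90 reads in the controls and 117, 76 and 97 in the libraries labelled Gata4 CKO. That is 3.30 ± 0.54 CPM against 4.65 ± 1.30 CPM (SD, n = 3 each). The log2 fold change was 0.49 ± 0.28 (SE, edgeR adjusted p = 0.671), it was 0.305 without Gata4 CKO 1, and it was 0.73 among the 3 libraries that share a column-label number. Those are Gata4 CKO 1 and controls 1 and 2, so values among them describe 1 Gata4 CKO library and are given in these paragraphs without p-values. The targeted gene was thus not lower where the labels say it was deleted. A whole lung holds cells in which the transgene is not active. By the labelled genotypes those cells still carry 1 deleted allele in Gata4 CKO and none in controls. Inactivity of the transgene alone thus does not account for a count that was not lower. Counts over the whole gene can also include exons outside the deleted part, so this count checks the labels only weakly. For this reason the groups are called by their labels here, and every direction rests on those labels.

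Xist, expressed from the inactive X chromosome of female cells, had 21820, 10322 and 50609 reads in control 2, Gata4 CKO 1 and Gata4 CKO 3, and at most 16 elsewhere. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were read in control 1, control 3 and Gata4 CKO 2, where Ddx3y had 2728, 3927 and 2523 reads. In the other 3 libraries Ddx3y, Uty and Eif2s3y had 0 reads, and Kdm5d had at most 1. Each group thus held embryos of both sexes.

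No gene passed the threshold when the libraries labelled Gata4 CKO were compared with controls. With edgeR, 0 of 17075 genes had an adjusted p under 0.05 (smallest 0.529). At unadjusted p under 0.05 there were 1482 genes, 643 higher and 839 lower, where chance alone gives 854. DESeq2 called 110 genes (45 higher, 65 lower), limma-voom called 0, and limma-voom with quality weights called 4460. Without Gata4 CKO 1, edgeR called 115 genes (75 higher, 40 lower), of which 20 were also called by DESeq2 on all libraries. With that library left out, no column-label number occurs in both groups. The number and the group therefore cannot be told apart in any fit without Gata4 CKO 1. The groups did not overlap for 16.8% of genes, where chance gives 10%.

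The 5 genes with the smallest p in each direction did not pass in edgeR (adjusted p = 0.529 for each). Trim67, a ubiquitin ligase of the tripartite motif family, stood at 9.65 ± 4.87 CPM in controls and 0.77 ± 0.27 CPM in libraries labelled Gata4 CKO (SD, n = 3 each), a log2 fold change of -3.61 ± 0.51 (SE). The gene (ENSMUSG00000036913, protein-coding) lies on chromosome 8 from 124793092 to 124834713, plus strand. Its control values were 11.9, 13.0 and 4.06 CPM. Egr3, an immediate early transcription factor, had a log2 fold change of -2.80, and Cdh4, a cadherin, of -1.62. Tenm4, a teneurin, had -0.84, and Fras1, a basement membrane protein (ENSMUSG00000034687, chromosome 5, 96373955 to 96784728, plus strand), had -0.90. On the other side were Apoc1, an apolipoprotein, at 1.70, Ctsf, a cathepsin, at 1.33, and Adamdec1, a secreted metalloprotease, at 1.31. Slc22a19, an organic anion transporter, stood at 1.25, and Sord, sorbitol dehydrogenase, at 0.75. DESeq2 gave all 10 an adjusted p of 0.0064 or less. Without Gata4 CKO 1, where label number and group cannot be told apart, edgeR gave adjusted p-values from 0.0308 (Ctsf and Fras1) to 0.0709 (Trim67 and Egr3).

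Among the 51 gene lists, 18 passed in camera, 9 higher and 9 lower. With an estimated correlation none did, and the smallest adjusted p was 0.364. Fry called 1 list. No member of any list passed over all genes.

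Proliferation genes were lower in the libraries labelled Gata4 CKO. All 30 mitosis genes and all 29 DNA replication genes had negative log2 fold changes. Mitosis genes fell by 1.12 on the log2 scale on average (camera adjusted p = 4.3e-16). The adjusted p was 0.47 with an estimated correlation. When adjusted over the list alone, 20 of the 30 passed, all lower. Mki67, a marker of cycling cells, was at 185.2 ± 65.0 CPM in controls and 85.2 ± 21.5 CPM in libraries labelled Gata4 CKO (SD, n = 3 each), a log2 fold change of -1.12 ± 0.30 (SE, adjusted p = 0.529). Top2a, the replication topoisomerase, stood at -1.34, Foxm1, a mitotic transcription factor, at -1.38, Anln at -1.36 and the spindle motor Kif11 at -1.14. DNA replication genes fell by 0.86 on average (camera adjusted p = 3e-13, and adjusted p = 0.47 with an estimated correlation). Of the 29, 9 passed when adjusted over the list alone, all lower. Clspn, a replication checkpoint mediator, had -1.51, and the helicase subunits Mcm4, Mcm5 and Mcm6 had -1.06, -1.07 and -0.79, with Mcm5 at -1.61 without Gata4 CKO 1. Control 3 lay among the libraries labelled Gata4 CKO for both lists. The mitosis score was 0.34, 0.43 and -0.76 in controls 1, 2 and 3 and -0.65, -1.75 and -0.99 in Gata4 CKO 1, 2 and 3 (exact permutation p = 0.2). Among the 3 libraries that share a column-label number, the means were -1.02 and -0.78.

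**Figure D1:**
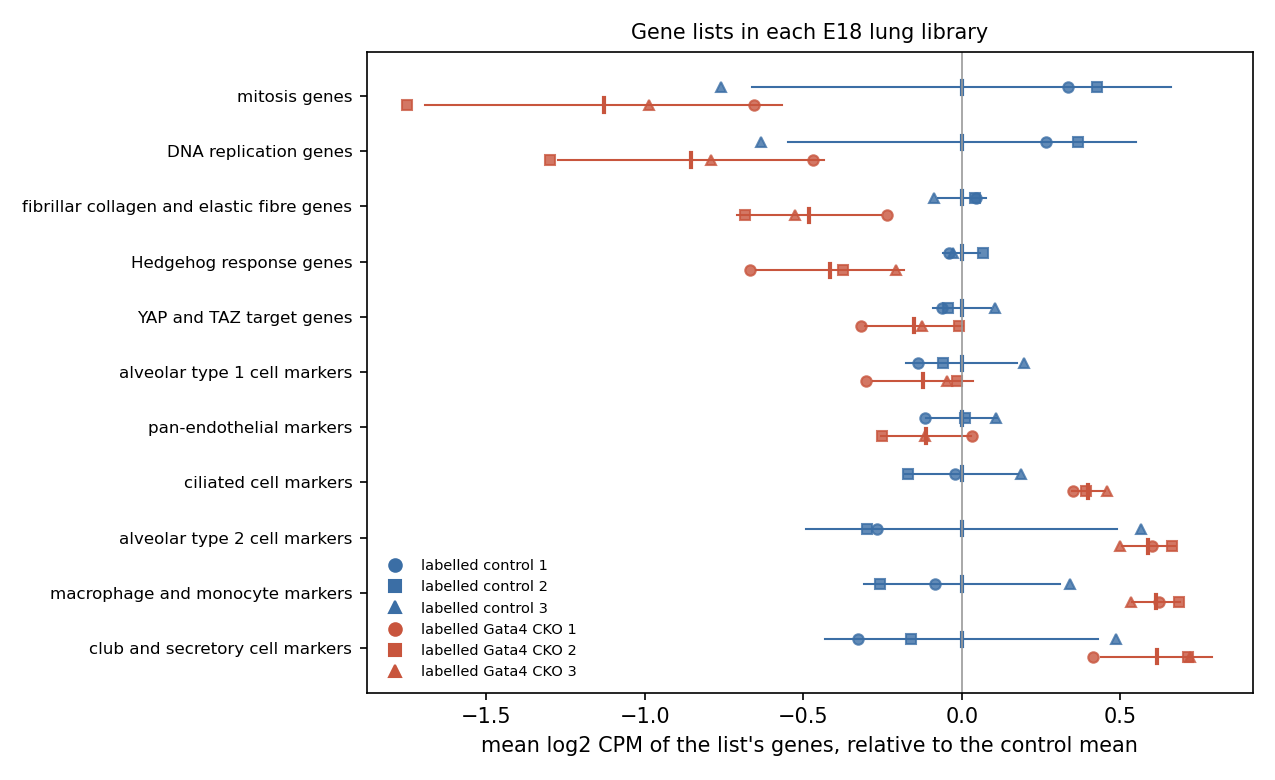
Mean log2 CPM of the genes of 11 lists in each library, relative to the control mean (x axis), with controls in blue and libraries labelled Gata4 CKO in red; vertical ticks are group means and lines are 1 SD (n = 3). Mitosis genes lie between -1.75 and -0.65 in the libraries labelled Gata4 CKO and at -0.76 in control 3, while Hedgehog response, collagen, macrophage and ciliated cell lists do not overlap between groups.

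Airway and alveolar type 2 epithelial markers were higher. All 20 alveolar type 2 markers had positive log2 fold changes, and the list rose by 0.53 on average (camera adjusted p = 1.27e-06, and adjusted p = 0.47 with an estimated correlation). None (0 of 20) passed when adjusted over the list alone. Sftpc, surfactant protein C, was at 7431 ± 2006 CPM in controls and 12530 ± 3520 CPM in libraries labelled Gata4 CKO (SD, n = 3 each, log2 fold change 0.75 ± 0.28, SE, adjusted p = 0.543). Sftpb, surfactant protein B, had 0.61, the calcium-binding S100g 1.498 and the fatty acid-binding Fabp5 0.74 (0.44 without Gata4 CKO 1). Club and secretory markers rose by 0.61 (camera adjusted p = 5.41e-06, and adjusted p = 0.47 with an estimated correlation), with 10 of 11 positive and 3 passing adjusted over the list alone. Cbr2 had 0.95, Scgb3a2 0.70, Cckar 0.43 and the secretoglobin Scgb1a1 0.74 (0.41 without control 1 and 1.56 without control 3). Ciliated markers rose by 0.42 (camera adjusted p = 3.71e-06, and adjusted p = 0.364 with an estimated correlation), with 16 of 18 positive and 0 passing adjusted over the list alone. Pifo had 0.79, Ccdc153 0.85, Sntn 0.63 and the ciliogenesis regulator Foxj1 0.29 (0.17 without Gata4 CKO 1 and 0.18 without control 2). The alveolar type 2 score was 0.57 in control 3, within the range from 0.50 to 0.66 of the libraries labelled Gata4 CKO, and without control 3 the mean was 0.91. Within the shared column-label number, the means were 0.90, 0.66 and 0.46 for alveolar type 2, club and ciliated markers.

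Alveolar type 1 markers did not pass, 0 of them passed when adjusted over the list alone, with 6 of 18 positive, a mean of -0.09 and a camera adjusted p of 0.186. Ager, a receptor of the flat gas-exchange cells, stood at 1189 ± 152.1 CPM in controls and 1217 ± 404.0 CPM in libraries labelled Gata4 CKO (SD, n = 3 each), a log2 fold change of 0.03. Hopx had 0.03, Pdpn -0.39 and the basement membrane collagen Col4a4 -0.51. Without Gata4 CKO 1, Ager, Hopx and Col4a4 had -0.27, -0.19 and -0.205, Ager and Hopx had 0.19 and 0.13 without Gata4 CKO 2, Col4a4 had -0.27 without control 3, and the list mean was 0.03 without control 3. Among libraries that share a column-label number, the list mean was -0.19.

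Fibrillar collagen and elastic fibre, diaphragmatic hernia, Hedgehog response and FGF and ERK response genes were lower. All 20 fibrillar collagen and elastic fibre genes had negative values, and the list fell by 0.47 (camera adjusted p = 3.1e-08, and adjusted p = 0.364 with an estimated correlation). Adjusted over the list alone, 3 passed, all lower, and 11 had non-overlapping groups. Fbn2, a fibrillin of developing microfibrils, was at 282.1 ± 134.9 CPM in controls and 90.5 ± 16.3 CPM in libraries labelled Gata4 CKO (SD, n = 3 each), a log2 fold change of -1.64 ± 0.38 (SE, adjusted p = 0.529). Lox, which crosslinks collagen and elastin, had -0.73, and Col5a1 had -0.64. Of the 24 tested genes linked to congenital diaphragmatic hernia, 20 had negative values, and the list fell by 0.31 (camera adjusted p = 1.5e-05, and adjusted p = 0.364 with an estimated correlation). When adjusted over the list alone 1 passed, Fras1, and Fbn1 had -0.50. All 11 Hedgehog response genes had negative values, and the list fell by 0.40 (camera adjusted p = 0.000445, and adjusted p = 0.364 with an estimated correlation). The transcription factors Gli2, Gli3 and Foxf1 had -0.76, -0.73 and -0.52, and 1 of the 11, Gli2, passed adjusted over the list alone. FGF and ERK response genes fell by 0.29 (camera adjusted p = 0.00281, and adjusted p = 0.364 with an estimated correlation), with 11 of 13 negative and 0 passing adjusted over the list alone. The feedback inhibitors Spry4 and Spred2 had -0.54 and -0.40, and the transcription factor Etv4 had -0.71. The means within the shared column-label number were -0.27 for collagen, -0.49 for hernia genes, -0.68 for Hedgehog and -0.30 for FGF and ERK. The FGF and ERK call ended with control 3 and Gata4 CKO 1 both left out (mean -0.24, adjusted p = 0.0872).

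YAP and TAZ target genes, a common readout of mechanical state, fell by 0.14 on average (camera adjusted p = 0.0312, and adjusted p = 0.47 with an estimated correlation). Of the 23 genes 16 were negative, and 0 passed adjusted over the list alone. Ccn1 was at 46.3 ± 7.44 CPM in controls and 31.3 ± 8.18 CPM in libraries labelled Gata4 CKO (SD, n = 3 each), a log2 fold change of -0.57 ± 0.22 (SE, adjusted p = 0.546). Ccn2 had -0.73, Amotl2 -0.59 and Asap1 -0.53. The call ended without control 3 (mean -0.07, adjusted p = 0.237) and without Gata4 CKO 1 (mean -0.08, adjusted p = 0.245). It also ended with the length and GC trends removed (mean -0.09, adjusted p = 0.102) and with quality weights (adjusted p = 0.405), and among libraries that share a column-label number the mean was -0.25.

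Macrophage and monocyte markers rose by 0.58 on average (camera adjusted p = 1.09e-07, and adjusted p = 0.364 with an estimated correlation). Of the 17 genes 15 were positive, and 5 passed adjusted over the list alone, all higher. Adgre1, the F4/80 antigen of macrophages, was at 9.68 ± 0.66 CPM in controls and 15.98 ± 0.79 CPM in libraries labelled Gata4 CKO (SD, n = 3 each), a log2 fold change of 0.72 ± 0.16 (SE, adjusted p = 0.529). Fcgr3, an immunoglobulin receptor, had 0.86 and Ms4a7 had 1.28. The list's score was 0.62, 0.69 and 0.54 in Gata4 CKO 1, 2 and 3 and -0.08, -0.26 and 0.34 in controls 1, 2 and 3, with an exact permutation p of 0.1, the smallest this design allows. Other lists had the same value, among them the collagen, hernia, Hedgehog, FGF and ERK, and ciliated lists. So did lists that camera did not call, such as pericyte, neuroendocrine and Notch response. Among libraries that share a column-label number the macrophage mean was 0.81. Cardiomyocyte genes rose by 0.53 (camera adjusted p = 0.000115, and adjusted p = 0.479 with an estimated correlation), with 12 of 13 positive and 0 passing adjusted over the list alone. Myh7, Myl4 and Sln, which encode muscle proteins, had 0.51, 0.55 and 0.97, with Myl4 at 0.33 without Gata4 CKO 2. The cardiomyocyte score was 0.48, 0.91 and 0.043 in Gata4 CKO 1, 2 and 3 and 0.11, 0.042 and -0.15 in controls 1, 2 and 3 (exact permutation p = 0.2). Gata4 CKO 3 thus lay within the range of the controls. Without Gata4 CKO 2, which scored highest, the mean was 0.31. Without Gata4 CKO 3 it was 0.85, and among libraries that share a column-label number it was 0.53. The cardiomyocyte call ended with quality weights (mean 0.15, adjusted p = 0.413) and with control 3 and Gata4 CKO 1 both left out (mean 0.45, adjusted p = 0.176), and over 25 settings the mean ranged from 0.11 to 1.13, past the threshold in 18.

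**Figure D2:**
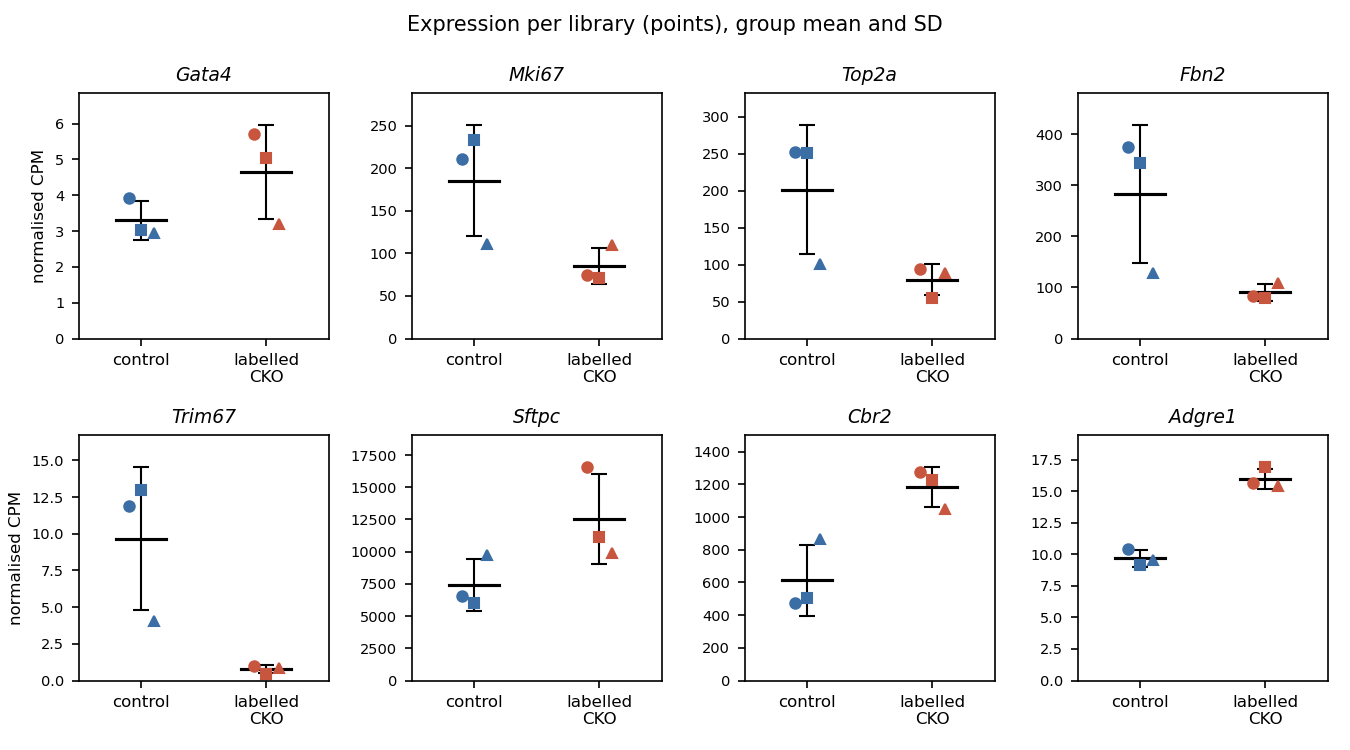
Normalised CPM of 8 genes in each library (y axes start at 0), with controls in blue and libraries labelled Gata4 CKO in red; circles, squares and triangles are replicates 1, 2 and 3, and black lines are group means with 1 SD. Gata4 is not lower in the libraries labelled Gata4 CKO, and control 3 lies close to them for Mki67 (111.2 CPM) and Fbn2 (127.3 CPM).

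Further lists passed in camera with calls that ended when 1 library was left out. Interferon response genes rose by 0.62 (camera adjusted p = 0.0149, and adjusted p = 0.529 with an estimated correlation), with 15 of 16 positive and 0 passing adjusted over the list alone. Ifit1 had 1.22 (0.78 without Gata4 CKO 1) and Mx1 1.095. The score was 1.25 in Gata4 CKO 1, and the mean was 0.03 without it (adjusted p = 0.776) and 0.69 without control 3 (adjusted p = 0.0542). Neutrophil markers rose by 0.49 (camera adjusted p = 0.0119, and adjusted p = 0.479 with an estimated correlation), with all 9 positive, 0 passing adjusted over the list alone, and S100a8 at 0.59 (0.34 without control 2 and 0.96 without control 3). That mean was 0.23 without control 2 and 0.28 without Gata4 CKO 1, neither past the threshold, and 0.82 without control 3. Hypoxia response genes rose by 0.21 (camera adjusted p = 0.0377, and adjusted p = 0.493 with an estimated correlation), with 17 of 20 positive, 0 passing adjusted over the list alone, and Bnip3 at 0.56. The hypoxia call ended without control 2 (0.16), control 3 (0.21), Gata4 CKO 1 (0.11) or Gata4 CKO 2 (0.18), and the mean was 0.31 without Gata4 CKO 3. Cholesterol synthesis genes fell by 0.22 (camera adjusted p = 0.0107, and adjusted p = 0.479 with an estimated correlation), with 15 of 18 negative and 0 passing adjusted over the list alone. Stard4, Idi1 and Cyp51 had -0.53, -0.75 (-0.50 without Gata4 CKO 1) and -0.42, and the call ended without control 2 (-0.13) or Gata4 CKO 2 (-0.15). TGF-beta response genes fell by 0.25 (camera adjusted p = 0.0193, and adjusted p = 0.364 with an estimated correlation), and were the list that fry called (adjusted p = 0.0306). Adjusted over the list alone, 6 of 13 passed lower, among them Ltbp2 (-0.54) and the growth factor Tgfb2 (-0.80). Its call ended without Gata4 CKO 1 (-0.29), 2 (-0.24) or 3 (-0.22). Hepatocyte genes were called higher (camera adjusted p = 0.038, and adjusted p = 0.479 with an estimated correlation) with a mean of 0.05, a median of 0.34 and 5 of 8 positive. Adjusted over the list alone 0 passed, and Trf, transferrin, had 0.84 (1.51 without control 3). The hepatocyte mean was 1.06 without control 1, and it was negative and not past the threshold without any other library. Among libraries that share a column-label number, the means were 1.32, 1.06, 0.34, -0.20, -0.20 and -0.69 for interferon, neutrophil, hypoxia, cholesterol, TGF-beta and hepatocyte genes. With the length and GC trends removed, the interferon (adjusted p = 0.0561), neutrophil (0.0998), hypoxia (0.067), TGF-beta (0.0716) and hepatocyte (0.0723) calls ended and the cholesterol call did not (0.0219). Quality weights, which were lowest for Gata4 CKO 1, ended the interferon (mean 0.0037), hypoxia (0.0019), cholesterol (-0.18) and hepatocyte (0.036) calls.

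The pan-endothelial, alveolar fibroblast, mesothelial and smooth muscle lists did not pass. Of the members of these 4 lists, Myh11 passed when adjusted over the list alone. Pan-endothelial markers had a mean of -0.09 (camera adjusted p = 0.202), with Pecam1 at -0.11 (-0.07 without Gata4 CKO 2) and Flt1 at -0.46. Without Gata4 CKO 1 the pan-endothelial mean was -0.18 and passed (adjusted p = 0.0288), while without control 1 it was -0.15, without control 3 it was -0.04 and without Gata4 CKO 2 it was -0.02, none past the threshold. Alveolar fibroblast markers had a mean of 0.0067, a median of -0.013 and a camera direction of lower (adjusted p = 0.98), with the growth factor receptor Pdgfra at -0.33 (-0.10 without Gata4 CKO 1). Mesothelial markers had 0.15 (adjusted p = 0.656), with Wt1 at 0.06 (-0.36 without Gata4 CKO 2 and 0.35 without Gata4 CKO 1). Smooth muscle genes had -0.22 (adjusted p = 0.0577), with Acta2 at -0.52 (-0.90 without Gata4 CKO 1 and -0.31 without Gata4 CKO 2), Myh11 at -0.73, Myocd at -1.09 and Smtn at -0.43. That list passed without control 1 (-0.22, adjusted p = 0.0451) or Gata4 CKO 1 (-0.28, adjusted p = 0.0377), in DESeq2 (adjusted p = 0.00354), limma-voom (0.0469) and limma-voom with quality weights (0.0316), and in 9 of 25 settings in all, with adjusted p from 0.000166 to 0.743. Car4, a marker of capillary aerocytes, had 0.19, but 1.12 without control 3, which stood at 59.1 CPM against 15.7 and 16.03 CPM in controls 1 and 2, and -0.12 without either of those (0.35 without Gata4 CKO 1 and 0.05 without Gata4 CKO 2). Within the shared column-label number, the means were 0.10, 0.04, -0.08 and -0.25 for endothelial, fibroblast, mesothelial and smooth muscle genes. The other lists that did not pass had means from -0.42 (cartilage) to 0.58 (basal and squamous cells), each with a camera adjusted p of 0.0577 or more.

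The second principal component of the 500 most variable genes separated the groups and the first did not. On the second, with 19.4% of the variance, controls 1, 2 and 3 scored -20.4, -12.6 and -3.23 and Gata4 CKO 1, 2 and 3 scored 15.3, 11.5 and 9.52. Control 3 had its highest Pearson r over genes with Gata4 CKO 3 (0.9866), above its values with control 1 (0.982) and control 2 (0.9769). Gata4 CKO 1 correlated with the other libraries at r from 0.944 to 0.9609, while the highest r of each other library was at least 0.986. The first component held 50.5% of the variance, with scores of 38.4 for Gata4 CKO 1, -25.3 for Gata4 CKO 2 and -13.5 for Gata4 CKO 3. Controls 1, 2 and 3 scored 2.58, 13 and -15.2 on it. Its sign thus followed the column-label number. Controls 1 and 2 and Gata4 CKO 1, which share a number, scored above the other libraries, also with 2000 genes. In Gata4 CKO 1 expression fell with transcript length relative to the other libraries (Spearman -0.645 across genes, which are not independent replicates), while the other libraries had values from 0.19 to 0.378. Ribosomal protein genes took 7.18% of its reads, against at most 4.23% in any other library. With the length and GC trends removed, edgeR called 0 genes (2252 at unadjusted p under 0.05), and 14 lists passed in camera in place of 18.

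**Figure D3:**
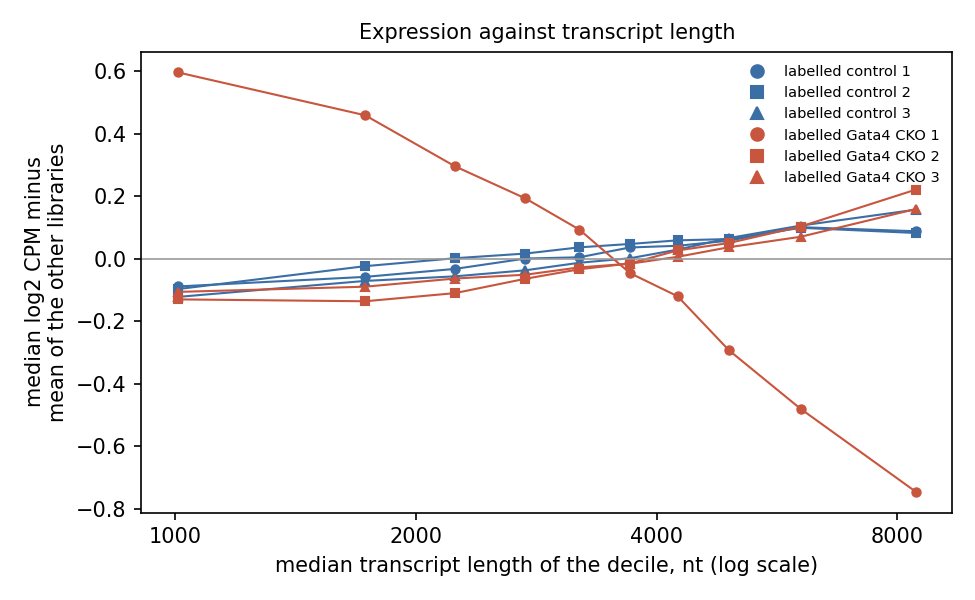
Median log2 CPM of each library minus the mean of the other libraries (y axis) in deciles of transcript length (x axis, nt, log scale), with controls in blue and libraries labelled Gata4 CKO in red. Gata4 CKO 1 runs from 0.596 in the shortest decile to -0.745 in the longest, and the other libraries stay between -0.136 and 0.221.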

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

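The length and GC offset, alone and with the label number as a term, control 1 and 2 against Gata4 CKO 2 and 3, and DESeq2 without Gata4 CKO 1 were tests chosen after the data were seen. For the named genes, 1516 values over the settings kept direction and side of the threshold, 386 passed where none had, and 44 turned sign. For the named lists, 435 kept both, 100 lost the call, 12 gained one and 27 turned sign. Mitosis genes ranged from -1.67 to -0.84 over 25 settings and passed in 23, DNA replication genes from -1.31 to -0.67 (23) and alveolar type 2 markers from 0.38 to 0.91 (23). Alveolar type 1 markers passed in 0, YAP and TAZ targets in 13. The mitosis, DNA replication and alveolar type 2 lists did not pass with an estimated correlation (camera adjusted p = 0.47 for each). Nor did they pass with fry (adjusted p = 0.229 for each). The settings in which they passed kept the preset correlation of camera. The number of settings passed therefore does not test how a call depends on that correlation. Where no cause is given, the cause was not tested. With 3 libraries per group, 52% of genes simulated as changed 2-fold were recovered. The simulation took each gene's spread from a trend with expression level, so real recovery may be lower. Trim67, with a log2 fold change of -3.61, was not called by edgeR. An uncalled gene may thus still differ by 2-fold or more.

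DESeq2 called 110 genes (45 higher, 65 lower, 79 at least 2-fold), with hepatocyte genes at -0.58. With quality weights limma-voom called 4460 (2196 higher, 2264 lower, 832 at least 2-fold), with weights of 0.0884 for Gata4 CKO 1 and 0.458 for control 3. There Gata4 was -0.014, Ager -0.16, Hopx -0.23, Hbb-y -1.44, alveolar type 1 markers 0.042 and YAP and TAZ targets -0.066. Plain limma-voom gave Ager -0.0048, Wt1 -0.082 and alveolar fibroblast markers -0.018. Without a filter hepatocyte genes were at -0.53, and under the stricter filter that list could not be tested. With Xist as a covariate, Xist was -0.028, Ager -0.0066, Hopx -0.015 and YAP and TAZ targets -0.11.

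With the label number as a term, 7308 genes passed (3296 higher, 4012 lower, 1655 at least 2-fold) and 9 lists, with Xist -0.055, Wt1 -0.78, YAP and TAZ targets -0.27, pan-endothelial markers 0.084 and mesothelial markers -0.099. With libraries of the shared number alone, 8663 passed (4162 higher, 4501 lower, 1779 at least 2-fold) and 8 lists. There Gata4 was 0.73, Xist -0.038, Wt1 -0.77, YAP and TAZ targets -0.25, hepatocyte genes -0.69, pan-endothelial markers 0.099 and mesothelial markers -0.084. Both fits set 1 Gata4 CKO library against controls 1 and 2 and take the spread from few libraries, so their counts and p-values take that library to vary as little as the others, and describe those libraries and not the groups. With the offset added to the term, 3895 passed (1934 higher, 1961 lower, 773 at least 2-fold) and 11 lists, with Wt1 -1.02, H2-Ab1 -0.047, YAP and TAZ targets -0.20 and mesothelial markers -0.13. The offset alone took the lists past the threshold from 18 to 14 and gave Ager -0.097, Hopx -0.13, YAP and TAZ targets -0.095 (call lost), hepatocyte genes -0.041 (call lost), alveolar fibroblast markers -0.0045 and a first component of 49.7%, against 46.7% with 2000 genes.

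Control 1 and 2 against Gata4 CKO 2 and 3 gave 4389 genes (2203 higher, 2186 lower, 974 at least 2-fold). There Ddx3y was 0.35, Uty 0.11, Kdm5d 0.38, Eif2s3y 0.35, Ager -0.16, Hopx -0.24, Col4a4 0.037, Hbb-y -1.93, alveolar type 1 markers 0.068, YAP and TAZ targets -0.0062 and hepatocyte genes -0.11. These 4 libraries also differ in label number between groups, as do those left in any fit without Gata4 CKO 1. DESeq2 without Gata4 CKO 1 called 1606 (689 higher, 917 lower, 305 at least 2-fold), with Kdm5d 0.057, Ager -0.28, Hopx -0.19, Hbb-y -1.46, hepatocyte genes -0.91 and alveolar fibroblast markers -0.028. With each library left out in turn, the counts ranged from 0 to 115 changed, 0 to 75 higher, 0 to 40 lower and 0 to 33 at least 2-fold, above 0 without Gata4 CKO 1 only. Of the 85 named genes, 18 turned sign or moved by over 1.5 times without Gata4 CKO 1, 12 without Gata4 CKO 2, 8 without Gata4 CKO 3, and 9, 12 and 12 without control 1, 2 and 3. The ranges were -0.27 to 0.19 for Ager, -0.12 to 1.12 for Car4, -1.96 to 0.58 for Alb, -0.19 to 0.14 for Hopx, -10.9 to 0.060 for Kdm5d, -1.44 to 2.39 for Hbb-y, -0.36 to 0.35 for Wt1 and -0.47 to 10.55 for Xist. They were -0.16 to 0.030 for alveolar type 1 markers, -0.21 to -0.073 for YAP and TAZ targets, -0.026 to 0.065 for alveolar fibroblast markers, -0.51 to 1.06 for hepatocyte genes, -0.018 to 0.24 for mesothelial markers, -0.18 to -0.018 for pan-endothelial markers and 0.31 to 0.85 for cardiomyocyte genes.

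With an estimated correlation 0 lists passed, and with fry 1. Their means stay the same by construction: mitosis -1.12, DNA replication -0.86, alveolar type 2 markers 0.53 and YAP and TAZ targets -0.14. Their adjusted p was 0.47 with an estimated correlation and 0.229 with fry.

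The replicate numbers do not pair the libraries: same-numbered libraries deviated from their group means with r of 0.111, -0.301 and 0.119. With the number as a block, edgeR called 0 genes (1191 at unadjusted p under 0.05) and 17 lists, with Ager -0.0097, Wt1 -0.041, alveolar fibroblast markers -0.020 and YAP and TAZ targets -0.15 (adjusted p = 0.0675).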

Other observations

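The fits with Xist as a covariate and with the column-label number, and the splits of the libraries, were chosen before the data were examined, while what each fit would show under an explanation was written after the results were seen. The other tests of explanations below were chosen after. The MHC class II genes H2-Eb1, H2-Ab1 and H2-DMb1 were called higher in the libraries labelled Gata4 CKO by DESeq2 and not by edgeR on all 6 libraries. They were picked after their values were seen, and MHC class II genes as a group were not tested. H2-Eb1 stood at 2.99 ± 0.85 CPM in controls and 9.53 ± 4.81 CPM in libraries labelled Gata4 CKO (SD, n = 3 each), a log2 fold change of 1.66 (DESeq2 adjusted p = 0.011, edgeR adjusted p = 0.529). H2-Ab1 had 1.72 and H2-DMb1 1.07 (DESeq2 adjusted p = 0.0141 and 0.0157), while in edgeR both had 0.529. Without Gata4 CKO 1, where label number and group cannot be told apart, edgeR gave H2-Ab1 2.08 (adjusted p = 0.0294). Among the libraries that share a column-label number H2-Ab1 had 0.635, with Gata4 CKO 1 at 4.84 CPM. Over 23 settings H2-Ab1 had adjusted p-values from 1.06e-12 to 1 and passed in 5. Alb, albumin, had 16.8 CPM in control 1 and at most 3.04 CPM in any other library, and was picked after its values were seen. Hbb-y, an embryonic globin, had 46.3 CPM in Gata4 CKO 1 and at most 10.6 CPM elsewhere.

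Gata4 CKO 1 stood apart from the other libraries. Transcript length and GC content accounted for 53.6% of the variance of its log2 deviation, against at most 18.6% in any other library, so a length and GC bias may be part of the reason. With both trends removed, its mean r with the other libraries was 0.9695, still below the lowest mean r of 0.9755 among the others. The trends removed thus did not account for all of its distance. They were smooth trends with the length and GC of the longest transcript, and bias of another form would remain. A length and GC bias as the whole reason therefore stays open. Its total count of 20833883 lay inside the range of the others, which argues against depth as a reason. The other Gata4 CKO libraries had a mean score of -19.4 on the first component, on the opposite side. Scores on a component are centred over the libraries, so a library far out pushes the others the opposite way. These scores therefore do not test a difference shared by the group. On the second component Gata4 CKO 1 scored 15.3, on the side of the other Gata4 CKO libraries. Whether anything else sets this library apart stays open.

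Mitosis genes were lower in the libraries labelled Gata4 CKO. With the length and GC trends removed the mean was -1.06, and with Xist as a covariate it was -1.38, both beyond the control SD of 0.661 and past the camera threshold at its preset correlation, which argues against length bias and embryo sex as the whole cause. With an estimated correlation the list itself did not pass (adjusted p = 0.47). Among the libraries that share a column-label number it was -1.02, but only 1 Gata4 CKO library is there, so this number and the group cannot be told apart. Control 3, whose label number differs from those of controls 1 and 2, had a score among those of the Gata4 CKO libraries, and the genotype stays open and untested as an explanation beyond this comparison.

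Macrophage and monocyte markers were higher in the libraries labelled Gata4 CKO. Globin reads took 1.08%, 0.724% and 0.684% in Gata4 CKO 1, 2 and 3 and 0.745%, 0.903% and 0.914% in the controls, and in 2 libraries, Gata4 CKO 2 and 3, the macrophage score exceeded the log2 globin share by 0.917 and 0.85 (control SD 0.306), which argues against residual blood as the whole cause, while in Gata4 CKO 1 (0.274) blood stays open. With the length and GC trends removed the mean was 0.52, beyond the control SD of 0.309 and past the camera threshold at its preset correlation (with an estimated correlation the list itself did not pass, adjusted p = 0.364), which argues against that bias as the whole cause. A lower share of 1 other cell type would raise the markers of all remaining types alike, but in 5 of 8 (pan-endothelial, alveolar fibroblast, mesothelial, smooth muscle and alveolar type 1) the score rose less than the macrophage score by 0.503 to 0.871, more than 2 control SD of each difference. Alveolar type 2, club and ciliated markers rose about as much as macrophage markers (differences 0.0252, -0.0015 and 0.214), so a fall of several other types together, more macrophages, more expression per macrophage and the genotype stay open.

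The 6 libraries can be split 3 against 3 in 10 ways, which is too few for a share under 0.05. The real split gave 0 genes in edgeR, so all 10 splits gave as many, and the highest other gave 12. At unadjusted p under 0.05 the real split gave 1482 genes and the highest other 2999, so 2 splits gave as many. For gene lists the real split gave 18 and the highest other 13, so 1 split gave as many. Every other split gave lists too, from 2 to 13, so camera at its preset correlation also called lists in groupings that mix the labels. The split with 12 and 2999 genes sets controls 1 and 2 and Gata4 CKO 1 against the rest, and so follows the column-label number. That points to a structure of the samples, and the mitosis mean in that split was -1.22.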
